A study of Drosophila melanogaster with 4 samples.

How the data were processed

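ChIP-seq peak lists of 3 antibodies (CP190, CG8436 and CG9740) in S2 cells were analysed. Groups were taken from the antibody field of the labels, with 1 library per antibody. The Input library was used by the authors as the reference for peak calling, per the series' design text, and its reads were not analysed here. Per the labels' protocols, sonicated nuclear lysates were immunoprecipitated with rat polyclonal antibodies against the Ibf proteins and a rabbit polyclonal antibody against CP190, and libraries were amplified by PCR. Reads amplified by PCR are not independent molecules. The genome build was dm3 and CASAVA 1.8.2 was used, per the submitters' processing notes. The aligner, the peak caller and its thresholds are not given in the sources used here.

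Each deposited file held a chromosome, a start and an end per peak, with no header, score, height, fold or p-value. The peaks were therefore compared by position, width and overlap only. The authors called peaks per library, so no replicate comparison could be made. Neighbouring peaks of a list lay at least 300 bp apart and none overlapped. In 7 CP190, 2 Ibf1 and 4 Ibf2 peaks the start equalled the end, so intervals were read as closed, and a width is the end minus the start plus 1 bp. Whether the starts count from 0 or from 1 could not be told from the files, and positions are printed as deposited. Widths under 50 bp occurred in 128 CP190, 45 Ibf1 and 42 Ibf2 peaks and were kept. The total read count of each library was unknown, so the depth behind a peak could not be stated. The precision of a share follows from the number of peaks, given as 95% exact (Clopper-Pearson) intervals that cover counting error only.

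The symbols Ibf1, Ibf2 and Cp190 for the 3 antibody targets were matched by locus tag or synonym in a RefSeq gene table of assembly Release 6. Since the peaks are in dm3, no coordinate of that table was used. The tests planned on promoters, divergent promoters, gene lists and sequence motifs need a genome or annotation of dm3 and were not run. The tests planned on peak scores were replaced by tests on peak width, because the lists hold no score.

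Peaks were taken to overlap when they shared at least 1 bp. Overlap was tested by placing the peaks of the first list at random within their own chromosome, widths kept, between the first and last position that any list called there, with 10000 draws and a one-sided empirical p. Overlapping peaks of the 3 lists were merged into regions, and shares of regions or peaks were compared with Fisher's exact test, two-sided, with the conditional odds ratio and its exact interval. Widths were compared by the difference of medians with a two-sided permutation test of 100000 resamples, and widths over shared regions by Spearman's rho and Pearson's r of log10 width with permutation p. Adjusted values follow Benjamini and Hochberg within each family: 3 overlap tests, 4 width tests, 3 correlations and 3 pairs of lists for each chromosome class. For chromosome X, peaks were counted against those on 2L, 2R, 3L, 3R and 4. The shuffle test was tested on simulated data with 200 simulations per comparison. With no planted overlap it passed 0.05 in 2% of simulations for Ibf1 in Ibf2, 5% for Ibf1 in CP190 and 5% for Ibf2 in CP190, and with 5% of peaks planted on the second list it passed in 100% for each of the 3 comparisons. The simulations used fewer draws and placed peaks by the test's own random rule, so they do not check that rule.

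The overlaps were recomputed with a minimum of 50% of the shorter peak or of both peaks, midpoints within 250 bp, or peaks within 500 bp. Random placement was varied with local placement 5 to 50 kb away and with circular shifts, where each chromosome's peaks moved by a separate offset. The overlaps were also recomputed on the placed chromosomes alone and with peaks at or above the median width of their list. The regions named in the text were chosen by a rule fixed before the data were examined: the 10 strongest regions called in all 3 lists and the 5 strongest called for CP190 alone, Ibf1 alone, Ibf2 alone and both Ibf proteins without CP190, of which the text gives a selection (regions with CP190 and Ibf2 alone were not part of the rule). The rule ranked by score, and width took its place. Also fixed before the data were examined were the tests of overlap, of merged regions and of the share of peaks on X between lists, and their alternatives on overlap rule, random placement, merging, placed chromosomes (for the overlaps) and Ibf peaks without CP190. Chosen after seeing the data were the tests on width, on unplaced sequence and on the Ibf share of CP190 peaks on X with their alternatives, the tests that leave out sites shared by the lists compared, every alternative at or above the median width, and the restriction of the merged regions to the placed chromosomes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.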

Results

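Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 3 proteins in Drosophila melanogaster S2 cells, a cultured line of embryonic origin with blood cell-like properties. CP190 is a zinc finger protein found at many insulators, the elements that limit contact between enhancers and promoters or between chromatin domains. The other two antibodies were raised against the products of CG8436 and CG9740, listed in the RefSeq gene table (Release 6) as Ibf1 and Ibf2 and named here by those symbols. The series comprised 1 immunoprecipitated library per antibody and 1 Input library of genomic DNA. The design implied 3 questions: whether Ibf1 and Ibf2 occupied the same sites, whether those sites were also CP190 sites, and whether occupancy differed between parts of the genome. The deposited peaks numbered 2067 for CP190, 618 for Ibf1 and 787 for Ibf2. Their median widths were 278 bp (interquartile range 191.5 to 339) for CP190, 231 bp (139 to 292) for Ibf1 and 267 bp (170.5 to 345) for Ibf2. The peaks covered 566.1 kb, 142.1 kb and 215.6 kb of the genome, respectively. The lists gave positions only, so the read depth of each library and the height of each peak were unknown. With no replicates, every p-value below describes positions or widths within these lists, and confidence intervals cover counting error only.

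Ibf1 and Ibf2 were called at nearly the same sites. Of 618 Ibf1 peaks, 613 (99.2%, 95% exact interval 98.1 to 99.7) overlapped an Ibf2 peak by at least 1 bp, against a mean of 2.04 ± 1.44 (SD, 10000 draws) when Ibf1 peaks were placed at random on the same chromosome arms. This was 301 times the random value, and none of the draws exceeded 11 (one-sided permutation of peak positions, Benjamini-Hochberg adjusted p = 0.0001 over 3 overlap tests, the smallest the draws can give). Placement was uniform along each chromosome and took no account of genes or repeats. The ratio therefore measures departure from uniform placement only, as do the ratios for CP190 below. In the other direction, 608 of 787 Ibf2 peaks (77.3%, 74.2 to 80.1) overlapped an Ibf1 peak. The peaks were also concentric: over 598 regions with a single peak of each protein, the midpoints lay a median of 8.5 bp apart (interquartile range 3.5 to 20), and 541 pairs (90.5%) lay within 50 bp. The Ibf1 peak lay wholly inside the Ibf2 peak in 565 of these regions (94.5%, 92.3 to 96.2), and the Ibf2 peak was the wider in 578 (96.7%, 94.9 to 98.0). Across the 606 regions shared by both proteins, peak widths were correlated (Spearman's rho = 0.81, Pearson's r of log10 width = 0.64, permutation p = 1e-05 for each, the smallest 100000 resamples can give, and 1e-05 after adjustment over 3 pairs of lists). Regions are not independent replicates, so this p describes the lists alone. Leaving out the 2 regions farthest from the median width gave rho = 0.80 and r = 0.63.

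The Ibf2 peaks without an Ibf1 peak were narrow. Their median width was 106 bp (57.5 to 168.5, n = 179), compared with 297.5 bp (238.8 to 363, n = 608) for Ibf2 peaks that overlapped one (permutation test, two-sided, adjusted p = 1e-05 over 4 width tests). When Ibf2 peaks were split into 3 groups of nearly equal size by width, in the narrowest tercile 103 of 262 (39.3%, 33.4 to 45.5) overlapped an Ibf1 peak, in the middle tercile 248 of 262 (94.7%, 91.2 to 97.1) did, and in the widest tercile 257 of 263 (97.7%, 95.1 to 99.2) did. The widest region called for Ibf2 alone was on arm 2R at positions 6726285 to 6726889 (dm3), followed by regions on X at 16229557 to 16230130 and on chromosome 4 at 679781 to 680254. Ibf1 alone was called at 5 regions of 15 to 57 bp, of which 4 were in Uextra, the unplaced sequence of this assembly, and 1 was on 2R at 15587308 to 15587322.

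Most Ibf sites were CP190 sites. A CP190 peak overlapped 519 of 618 Ibf1 peaks (84.0%, 80.9 to 86.8) and 625 of 787 Ibf2 peaks (79.4%, 76.4 to 82.2). Random placement gave means of 5.02 ± 2.23 and 7.0 ± 2.63 peaks (SD, 10000 draws), so the observed overlaps were 103 and 89.3 times the random values (one-sided permutations of peak positions, adjusted p = 0.0001 for each). The midpoints of Ibf1 and CP190 peaks lay a median of 17.5 bp apart over 513 single-peak regions, and those of Ibf2 and CP190 peaks 20.5 bp apart over 618. The widths were correlated less closely than those of the Ibf pair: rho was 0.41 and r 0.38 for Ibf1 with CP190 over 519 regions, and 0.37 and 0.23 (r = 0.225) for Ibf2 with CP190 over 622 regions (permutation p = 1e-05 for each before and after adjustment). The difference between these correlations was not tested. All 3 lists had been called against 1 Input library, so any calls that its own irregularities produced would be shared between lists. The size of that share was not measured here.

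**Figure D1:**
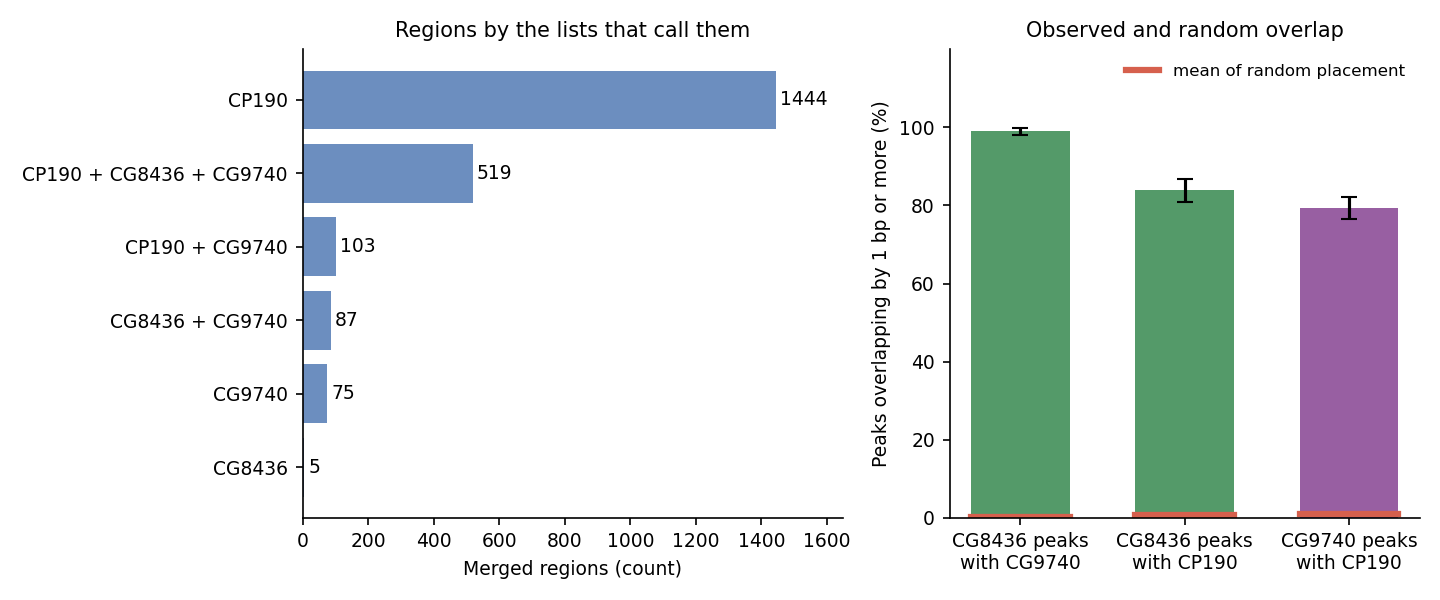
Left, number of merged regions by the lists that call them (horizontal axis, count). Right, percentage of peaks overlapping a peak of the second list, with 95% exact binomial intervals as error bars and the mean of 10000 random placements as red lines: the 3 observed values are 99.2%, 84.0% and 79.4%, and the random means lie near the axis.

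In the opposite direction, Ibf peaks were called at a minority of CP190 peaks. An Ibf2 peak overlapped 623 of 2067 CP190 peaks (30.1%, 28.2 to 32.2), and an Ibf1 peak overlapped 515 (24.9%, 23.1 to 26.8). Each of the 515 CP190 peaks with Ibf1 also had Ibf2, 108 had Ibf2 alone, 0 had Ibf1 alone and 1444 had neither. When overlapping peaks of the 3 lists were merged, 2233 regions resulted. CP190 alone was called at 1444 of them (64.7%), all 3 proteins at 519 (23.2%), CP190 with Ibf2 at 103, both Ibf proteins without CP190 at 87, Ibf2 alone at 75 and Ibf1 alone at 5. CP190 was called at 519 of the 606 regions with both Ibf proteins (85.6%, 82.6 to 88.3) and at 103 of the 183 regions with exactly 1 of them (56.3%, 48.8 to 63.6). The difference was 29.4 percentage points, with an odds ratio of 4.62 (3.14 to 6.81, Fisher's exact test, two-sided, p = 8.52e-16). Of the 183 regions, 178 had Ibf2 alone, and Ibf2 peaks without Ibf1 were narrow. CP190 overlapped 163 of 262 Ibf2 peaks (62.2%) in the narrowest tercile and 236 of 263 (89.7%) in the widest. Width was not matched in the comparison, so it does not separate the number of Ibf proteins from peak width. CP190 was called at 0 of the 5 Ibf1-only regions (exact upper limit 52.2%) and at 103 of the 178 Ibf2-only regions (57.9%, Fisher's exact test, two-sided, p = 0.0149). On the placed arms alone a single Ibf1-only region remained, and this second difference could not be resolved (Fisher's exact test, p = 0.431).

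CP190 peaks that carried an Ibf peak were wider than those that did not. The median width was 324 bp (267.5 to 396, n = 623) with an Ibf peak and 256 bp (168 to 315, n = 1444) without, a difference of 68 bp (permutation test, two-sided, adjusted p = 1e-05). In the narrowest tercile of CP190 peaks 110 of 689 (16.0%, 13.3 to 18.9) had an Ibf peak, in the middle tercile 181 (26.3%, 23.02 to 29.7), and in the widest tercile 332 (48.2%, 44.4 to 52.0). Ibf peaks with CP190 were likewise wider than those without. For Ibf1 the medians were 246 bp (n = 519) and 97 bp (n = 99), and for Ibf2 they were 289 bp (n = 625) and 177.5 bp (n = 162), with adjusted p = 1e-05 for each permutation test. Width depends on the calling threshold as well as on the signal, and the lists hold no score by which to separate them.

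**Figure D2:**
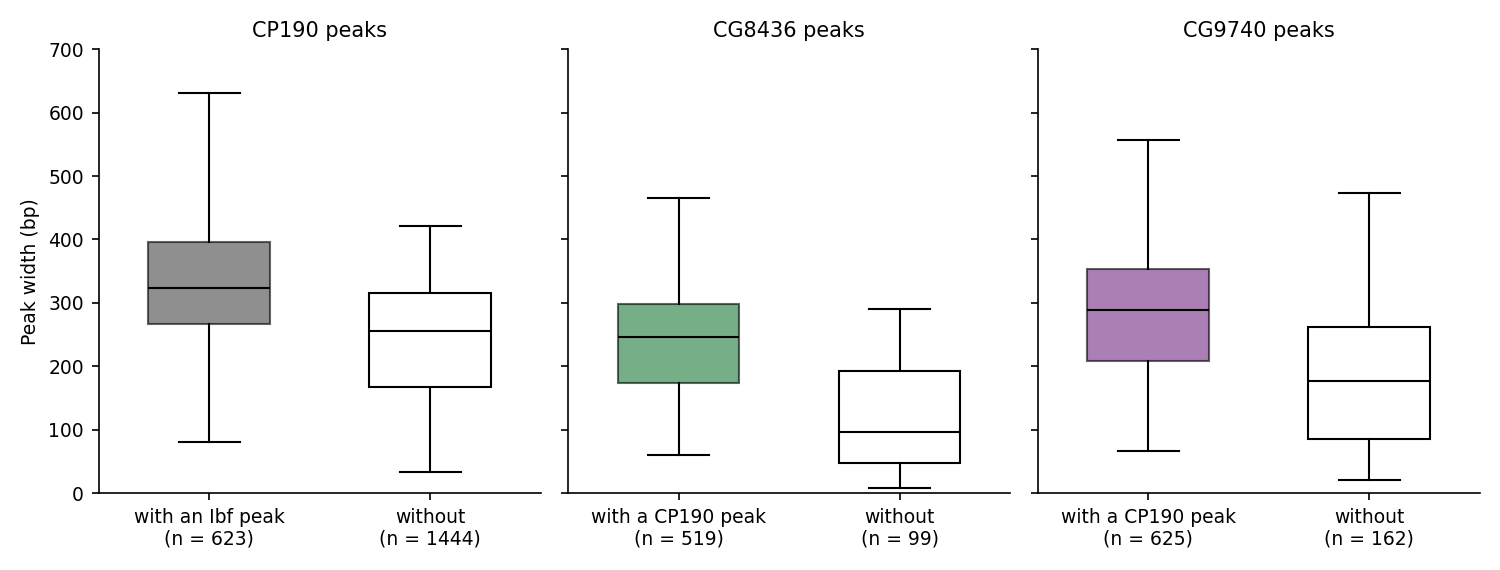
Width in bp of the called peaks, split by overlap with an Ibf peak (CP190) or with a CP190 peak (CG8436, which is Ibf1, and CG9740, which is Ibf2). Boxes span the quartiles with the median as a line, and whiskers run from the 5th to the 95th percentile: the median is higher with the partner than without it in each list, 324 against 256 bp for CP190.

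The widest CP190 peak among the 519 regions called in all 3 lists spanned 1424 bp in a region on 2R at 21076986 to 21078416, where the Ibf1 and Ibf2 peaks spanned 1292 and 1415 bp. A region on 3R at 13442205 to 13443245 was similar, with widths of 1041 bp for CP190, 965 bp for Ibf1 and 1014 bp for Ibf2. In others the CP190 peak extended far beyond the Ibf peaks. On X at 1180184 to 1181430 a CP190 peak of 1247 bp overlapped an Ibf1 peak of 161 bp and an Ibf2 peak of 266 bp, and on 2L at 73034 to 74170 the widths were 1137, 61 and 182 bp. Of the 10 regions ranked first by CP190 width, 6 were on 3R, and 1 was on chromosome 4 at 1133440 to 1134277. Among regions called for CP190 alone, the widest lay on 3L at 16044054 to 16045153 (1100 bp) and on 3R at 27046238 to 27047075 (838 bp). Both Ibf proteins were called without CP190 at 3R 5084027 to 5085102, with an Ibf1 peak of 448 bp and an Ibf2 peak of 1076 bp, and at 2R 19766365 to 19766930, with peaks of 521 and 566 bp. These positions are given as deposited, in dm3. An annotation of that build was not used here, so the genes at these regions are not named.

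A smaller share of Ibf peaks than of CP190 peaks lay on chromosome X. Of the peaks placed on 2L, 2R, 3L, 3R, 4 and X, those on X made up 62 of 571 for Ibf1 (10.9%, 8.43 to 13.7), 88 of 739 for Ibf2 (11.9%, 9.66 to 14.5) and 332 of 2011 for CP190 (16.5%, 14.9 to 18.2). The share on X differed by -5.65 percentage points between Ibf1 and CP190 (Ibf1 minus CP190), with an odds ratio of 0.616 (0.454 to 0.826, Fisher's exact test, two-sided, adjusted p = 0.00226 over 3 pairs). For Ibf2 minus CP190 it was -4.60 points, with an odds ratio of 0.684 (0.525 to 0.883, Fisher's exact test, adjusted p = 0.00415). Ibf1 minus Ibf2 was -1.05 points. As most of their sites are shared, they were compared through the Ibf2 peaks that had an Ibf1 peak, 62 of 88 on X (70.5%) and 503 of 651 on the autosomes (77.3%), an odds ratio of 0.702 whose interval (0.420 to 1.20) includes 1 (Fisher's exact test, two-sided, p = 0.180). The difference from CP190 was -9.69 points for Ibf1 (6 of 88 peaks on X) and -8.72 for Ibf2 (12 of 154) when only Ibf peaks without CP190 were counted. It was -8.84 and -9.77 points among peaks at or above the median width of their list. Both filters act unevenly on X, so neither is separate support. CP190 overlapped 90.3% of Ibf1 and 86.4% of Ibf2 peaks on X, against 84.0% and 79.4% of all. Ibf2 peaks were narrower on X (median 230 bp against 274 bp on autosomes), unlike CP190 peaks (289 against 275 bp). Because the lists share sites, the comparison was repeated among CP190 peaks alone. An Ibf peak overlapped 75 of 332 CP190 peaks on X (22.6%, 18.2 to 27.5) and 509 of 1679 on the autosomes (30.3%, 28.1 to 32.6), with an odds ratio of 0.671 (0.501 to 0.891, Fisher's exact test, two-sided, p = 0.00442). Among CP190 peaks at or above the median width the shares were 30.3% and 43.5%, with an odds ratio of 0.563 (0.392 to 0.802, Fisher's exact test, two-sided, p = 0.000924). Over the 4 large autosome arms the share ranged from 29.3% on 2L and 3R to 31.0% on 3L, a spread no larger than that given by permuting Ibf status over peaks (permutation p = 0.936). S2 cells carry fewer copies of X than of the autosomes, and the lists hold no value by which a peak could be scaled to copy number.

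**Figure D3:**
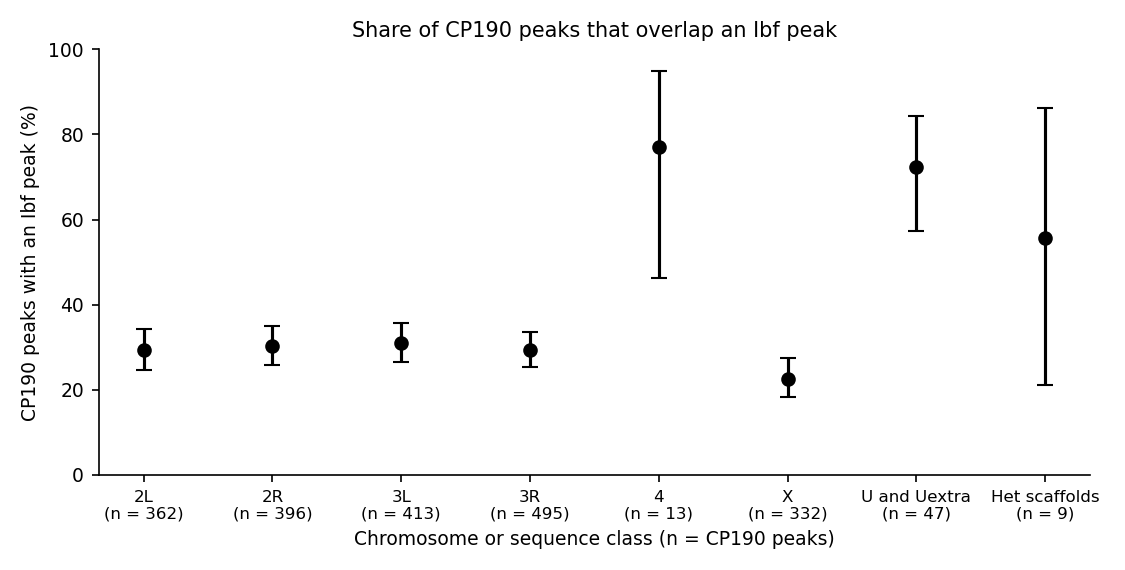
Percentage of CP190 peaks that overlap an Ibf peak (vertical axis) by chromosome arm or sequence class, with 95% exact binomial intervals as error bars and the number of CP190 peaks under each label. The 4 large autosome arms lie between 29.3% and 31.0%, X at 22.6%, chromosome 4 at 76.9% and the unplaced sequence at 72.3%.

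A larger share of Ibf peaks than of CP190 peaks lay in unplaced sequence (U and Uextra, contigs that could not be assigned to a chromosome, many of them repeats). These held 42 of 618 Ibf1 peaks (6.80%, 4.94 to 9.08), 41 of 787 Ibf2 peaks (5.21%, 3.76 to 7.001) and 47 of 2067 CP190 peaks (2.27%, 1.68 to 3.01). The counts themselves were close, so the larger Ibf shares go with fewer Ibf than CP190 peaks elsewhere. The odds ratio against CP190 was 3.13 for Ibf1 (1.99 to 4.91, Fisher's exact test, two-sided, adjusted p = 1.47e-06 over 3 pairs) and 2.36 for Ibf2 (1.50 to 3.70, adjusted p = 0.000203). These lists share sites, and among CP190 peaks alone an Ibf peak overlapped 34 of 47 in unplaced sequence (72.3%, 57.4 to 84.4) and 584 of 2011 on the placed arms (29.0%, 27.1 to 31.1, odds ratio 6.38, 3.26 to 13.3, Fisher's exact test, two-sided, p = 1.75e-09). Between the whole Ibf1 and Ibf2 lists no difference in this share was resolved (odds ratio 1.33, 0.83 to 2.12, Fisher's exact test, two-sided, adjusted p = 0.212). Of regions with 1 Ibf protein, 4 of the 5 Ibf1-only and 3 of the 178 Ibf2-only regions were unplaced (Fisher's exact test, two-sided, p = 3.82e-06). That contrast was chosen after seeing the data and rests on 5 Ibf1-only regions of 15 to 57 bp. Of the 57 merged regions in unplaced sequence, 31 were called in all 3 lists, 13 for CP190 alone, 6 for both Ibf proteins and 4 for Ibf1 alone, and 3 had CP190 with Ibf2. The Het scaffolds held 9 CP190 peaks, 4 Ibf1 peaks and 5 Ibf2 peaks. Restricting the lists to the placed chromosomes left the overlaps at 99.8% for Ibf1 with Ibf2, 84.6% for Ibf1 with CP190 and 79.2% for Ibf2 with CP190.

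**Figure D4:**
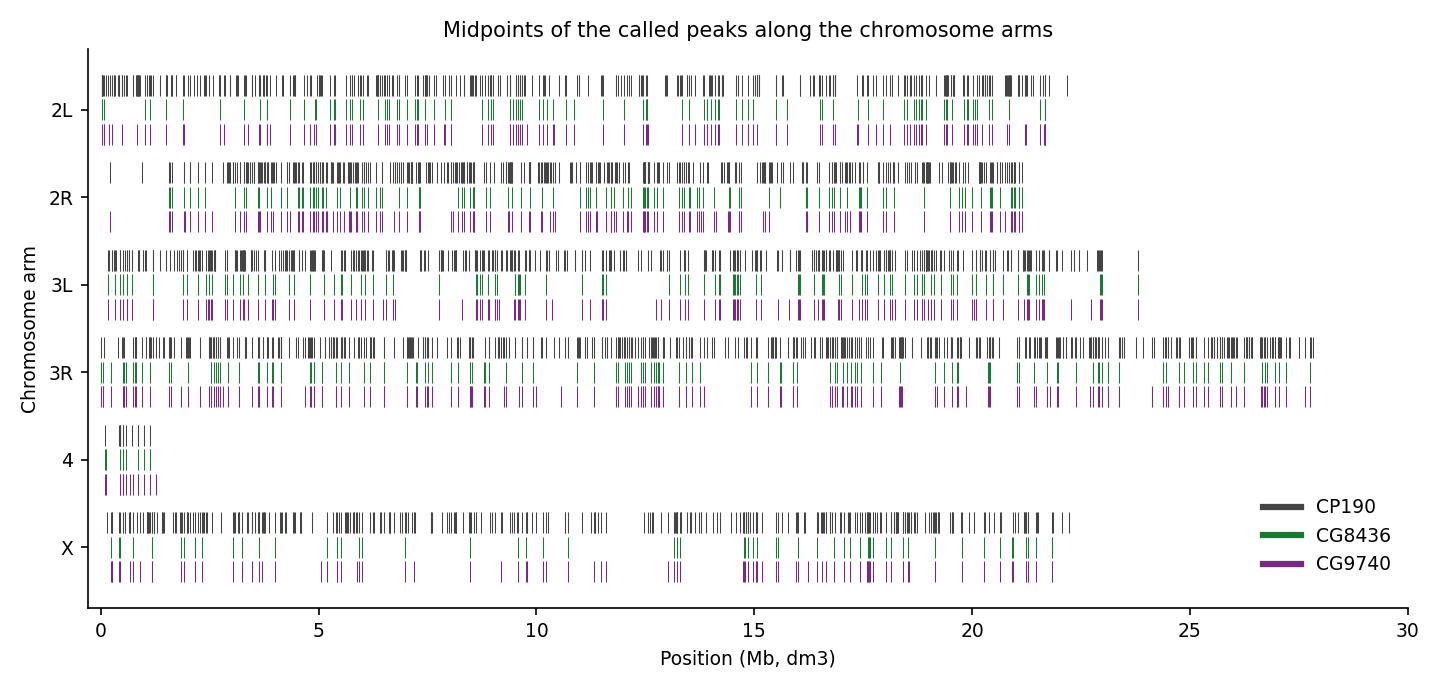
Midpoints of the called peaks (vertical ticks) along the 6 placed chromosome arms, with the position in Mb of dm3 on the horizontal axis and 1 row of ticks per list on each arm. The 2067 CP190 peaks include 2011 on these arms, compared with 571 for Ibf1 (CG8436) and 739 for Ibf2 (CG9740).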

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

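The tests in this part on unplaced sequence, on widths on X and on Ibf2 peaks without Ibf1 were specified before their own results were seen, but after the counts of peaks per chromosome. The choice to compare the lists in unplaced sequence, and the Ibf share of CP190 peaks on X, came after seeing those counts.

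CP190 peaks on X carried an Ibf peak less often than those on the autosomes (odds ratio 0.671, a difference between chromosomes in the same contrast). A loss of weak Ibf peaks at a fixed threshold may contribute, although the deficit stayed within terciles of CP190 peak width (Mantel-Haenszel odds ratio 0.557, 0.416 to 0.747) and CP190 peaks were no narrower on X (median 289 bp) than on autosomes (275 bp, permutation p = 0.0557). The bound set beforehand would exclude the explanation at that odds ratio, but Ibf2 width followed CP190 width only in part (rho = 0.37), so terciles of CP190 width do not equalise the Ibf signal. Ibf2 peaks were themselves narrower on X, with medians of 230 bp (n = 88) against 274 bp (n = 651), a difference of -44 bp (permutation test, two-sided, p = 0.00616, adjusted p = 0.0103 over 5 tests). A lower Ibf signal on X under a common threshold therefore stays open, whether from copy number, the antibodies or occupancy, and no biological explanation was tested.

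The unplaced sequence held a larger share of Ibf peaks than of CP190 peaks (odds ratios 3.13 for Ibf1 and 2.36 for Ibf2, a difference between the antibodies). The counts there were close, at 47 for CP190, 42 for Ibf1 and 41 for Ibf2, while the Ibf lists were shorter elsewhere. Background common to the 3 libraries, for example from repeats or from the single Input, may be a source. It predicts that Ibf regions there are called in all 3 lists more often than on the placed arms. The shares were 31 of 44 (70.5%) and 484 of 738 (65.6%), with an odds ratio of 1.25 (0.623 to 2.65, Fisher's exact test, two-sided, p = 0.624). The interval includes 1, so among regions with an Ibf peak no difference was resolved in either direction. Among CP190 peaks, an Ibf peak overlapped 34 of 47 there and 584 of 2011 on the placed arms. That odds ratio was 6.38 (3.26 to 13.3, Fisher's exact test, two-sided, p = 1.75e-09), a direction that common background would also give. Sites bound by all 3 proteins would also be called in all 3 lists. Neither comparison can therefore separate background from binding, and the question stays open. Binding in heterochromatic repeats, which is what the design would call biological, was not tested.

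A further pattern is the set of 179 Ibf2 peaks without an Ibf1 peak. A candidate explanation is 1 calling threshold applied to a weaker Ibf1 library, which predicts that these peaks are narrow. Their median width differed by -191.5 bp from that of Ibf2 peaks with Ibf1 (permutation test, two-sided, p = 1e-05), the comparison already given above, but weak sites of Ibf2 alone would be narrow too, so it does not separate these explanations. The Ibf2 peak was also the wider in 96.7% of shared regions. In the widest tercile of Ibf2 peaks 6 of 263 lacked Ibf1, so sites of Ibf2 alone are not excluded for those. Recognition of both proteins by one antibody was not tested, since it needs cells without one of the proteins.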

How the results depend on the processing

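No paired analysis was possible because each antibody had 1 library, and for the same reason no replicate could be left out. Of 63 alternative values over 19 results, 60 kept their direction and their side of the threshold. These are not all separate checks. Counting Ibf2 alone repeats the main Ibf share of CP190 peaks on X, since no CP190 peak had Ibf1 alone. Local placement and circular shifts change the random value but not the overlap itself. The filters on X act unevenly, as stated above. The difference between Ibf1 and Ibf2 in the share of peaks on X, which passed no threshold in any setting, changed sign from -1.05 to 0.930 percentage points among peaks at or above the median width, and the cause was not tested. The overlaps ranged from 79.8% to 99.8% for Ibf1 with Ibf2, from 62.1% to 85.3% for Ibf1 with CP190 and from 61.0% to 81.1% for Ibf2 with CP190, the lowest value each time when at least 50% of both peaks had to overlap. The lowest ratio to random placement was 32.6, for Ibf2 with CP190 and peaks within 500 bp. The 2 alternatives that lost their call both concern CP190 at Ibf1-only against Ibf2-only regions. The difference was -57.2 percentage points on the placed chromosomes alone, where 1 Ibf1-only region remained, and -48.4 points among peaks at or above the median width of their list (Fisher's exact test, two-sided, p = 0.431 and 0.0602), against -57.9 points with all peaks. The Ibf1-only regions with all peaks are 15 to 57 bp wide, under the median of 231 bp, so the width filter removes them and its 5 Ibf1-only regions are ones whose Ibf2 peak was filtered out. That alternative therefore does not test the regions named. Both alternatives were chosen after seeing the data, and over all alternatives p ranged from 0.00767 to 0.431. The alternatives planned on peak scores, random promoters, promoter windows, gene lists and motifs were not run, because the lists hold no score and no dm3 genome was used. Read depth, which limits how many weak sites could be called, was unknown.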

Other observations

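The tests in this part on chromosome 4, on spacing and on stretches without peaks were chosen after seeing the peak positions, and the test of neighbouring peaks was specified before its result was seen.

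Chromosome 4, a small and largely heterochromatic chromosome, had few CP190 peaks but most carried an Ibf peak. The count was 10 of 13 (76.9%, 46.2 to 94.96), compared with 499 of 1666 (29.95%) on the 4 large autosome arms, an odds ratio of 7.79 (1.99 to 44.2, Fisher's exact test, two-sided, p = 0.000682, adjusted p = 0.00171 over 5 tests). Ibf2 was called at 14 places there and Ibf1 at 10, so Ibf2 peaks outnumbered CP190 peaks on this chromosome alone among the placed arms. In unplaced sequence 34 of 47 CP190 peaks (72.3%, 57.4 to 84.4) had an Ibf peak, and on the Het scaffolds 5 of 9 did. A hypothesis is that CP190 sites in repeat-rich sequence more often carry Ibf proteins, but repeats can also produce shared calls, and the odds ratio of 7.79 rests on 13 peaks.

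CP190 peaks with an Ibf peak tended to follow one another along the arms. Among 1910 pairs of neighbouring CP190 peaks over 2 kb apart, 185 had an Ibf peak at both members, against 163.2 ± 9.09 (SD) when the status was permuted within each arm (permutation test, two-sided, p = 0.0238, adjusted p = 0.0298 over 5 tests). A modest local grouping of sites that carry Ibf proteins remains a hypothesis from 1 library per antibody. The permutation took no account of CP190 peak width. The share with an Ibf peak rose from 16.0% in the narrowest to 48.2% in the widest tercile of CP190 peaks. Grouping of wide CP190 peaks was therefore not separated from grouping of Ibf sites. Peaks of each list also lay closer together than at random: 78 of 739 Ibf2 peaks (10.6%) had another Ibf2 peak within 5 kb, against 46.6 ± 9.27 (SD, 1000 draws, one-sided permutation p = 0.000999, the smallest these draws can give), 48 of 571 Ibf1 peaks did against 28.3 ± 7.38 (p = 0.00999), and 362 of 2011 CP190 peaks did against 316.8 ± 21.6 (p = 0.0190). Random placement took no account of genes or repeats, since no dm3 genome or annotation was used. The p-values of these spacing permutations were not adjusted. A broad site called as separate peaks was not told apart from separate sites.

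The longest stretch without a CP190 peak was on X at 11589235 to 12477187, 888 kb, against a mean longest stretch of 424 ± 81.9 kb (SD) when the 332 peaks were placed at random (one-sided permutation p = 0.0008, adjusted p = 0.0016 over 6 arms). No Ibf peak lay in it either, which adds little. On X, CP190 overlapped 56 of 62 Ibf1 and 76 of 88 Ibf2 peaks, so few could lie in a stretch without CP190. Stretches of 735.5 kb on 2R at 207689 to 943172 and 825.1 kb on 3L at 22975536 to 23800684 also exceeded random placement (permutation tests, adjusted p = 0.0012 for each), near the start of the 2R and the end of the 3L sequence, and the longest stretches on 2L, 3R and 4 did not (adjusted p from 0.123 to 0.296). The window of 1 Mb with the most CP190 peaks was 3 to 4 Mb on 2R, with 35 peaks against a mean highest count of 28.96 in random placement (1000 draws, one-sided permutation p = 0.0150). The window with the most Ibf peaks was 12 to 13 Mb on 3R, with 17 Ibf2, 13 Ibf1 and 26 CP190 peaks, but random placement reached as many Ibf peaks in some window often enough to leave chance open (permutation p = 0.0699 for Ibf2 and 0.255 for Ibf1). The mitochondrial genome held 1 Ibf1 peak, at 3576 to 3630, and 2 Ibf2 peaks, at 1777 to 1901 and 3565 to 3640. The Ibf1 peak lay inside an Ibf2 peak, and the source of these calls was not tested. CP190 had 0 of 2067 peaks there (exact 95% upper limit 0.178%). The exact intervals for Ibf1 (0.0041 to 0.898%) and Ibf2 (0.0308 to 0.915%) overlap that of CP190, and the difference between the lists was not tested.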
